A study of Mus musculus with 6 samples.

How the data were processed

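The series compared megakaryocytes grown from progenitors of mouse fetal liver, 3 samples of a Gata-1 knock down and 3 of wild type, each measured on 1 Affymetrix mouse array. Groups and replicate letters were taken from the sample titles. The deposited table of the whole series holds 45101 probe sets with values of intensity on a linear scale, as the values themselves show. The mean of each deposited column, with 2% of the probe sets trimmed at each end, was 500.0 on every array, so a common scaling had been applied by the authors. The software that made the signals, and any genome build, are not given in the sources used here.

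Signals were tested as log2(signal + 32). The medians of the 6 arrays on that scale spanned 0.346, above the limit of 0.2 set before the data were examined, so the arrays were quantile normalized. Quantile normalization gives all arrays the same distribution and so removes any shift common to all genes. Mean ± SD values are of the signals as deposited, and log2 fold changes are of the normalized values with the offset, which understates the change of dim genes. Of the 5045 called genes, 10 had deposited group means in the opposite order to the fitted change, and the largest log2 fold change among them was 0.212 in size. The 64 control probe sets were left out of the test, as were probe sets whose mean log2 value over the 6 arrays lay below the 30th percentile, which left 31526.

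Groups were compared with limma (version 3.58.1 in R 4.3.3), with lmFit and eBayes with an intensity trend, group as the only term, a two-sided test and Benjamini-Hochberg adjustment over the probe sets tested, at an adjusted p of 0.05. Standard errors of log2 fold changes come from that fit. A replicate letter was not used as a block. Gene lists were compared with the other genes by limma's camera with a preset inter-gene correlation of 0.01 and adjustment over the 20 lists that had at least 5 tested members. A list member was said to rise or fall only where its own adjusted p passed over all probe sets tested.

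A platform annotation named 1 gene symbol for 34945 probe sets, several for 932 and none for 9160, the controls aside. Symbols were updated through gene numbers with a table of the GRCm38.p6 assembly, which was used only for names and for the order of genes, and no coordinates are given since no build is named for the array. Of 597 list entries, 555 matched a probe set and 512 were tested. A gene without a named probe set here is unnamed in this annotation and may still be on the array. Each gene was represented by its probe set with the highest mean over the 6 arrays among those that name 1 gene. Of 6532 genes with several tested probe sets, 90 had probe sets called in opposite directions. A call may rest on some of a gene's probe sets only. Among the genes named below by a rule fixed in advance, 1 of 3 tested probe sets was called for Lss. For Alad, Cdkn1b, Col4a1, Ddit3 and Fosl2 it was 1 of 2, and for Afp 2 of 4.

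The genes named are Gata1, the 12 genes with the largest rise and the 12 with the largest fall among called genes whose arrays did not overlap, up to 4 called members of each list with the largest changes, or 2 where none was called, a few genes fixed in advance, of which 1 is not reported here, and all sex-linked markers. Predicted genes were not named. Genes outside that rule are marked as named after their values were seen. A gene was within background in a group if its signal lay at or below the highest of the 27 bacterial control probe sets on each array of that group. Its fold change is then a bound, as it is for a gene at or below that control on 2 of 3 arrays of a group, written as at least, from the brighter group's mean against the mean of the higher, on each array, of that control signal and the gene's own, as means of normalized log2 values.

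RNA quality was checked with the control probe sets of beta-actin and Gapdh. The log2 signal at the 3' end minus that at the 5' end lay between 0.12 and 0.25 for beta-actin and between -0.31 and -0.19 for Gapdh over the 6 arrays. The median SD between arrays of a group was 0.203 on the log2 scale in knockdown and 0.131 in wild type. No pair of arrays in a group shared more than 0.233% identical signals.

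The test was tried on simulated data with changes put into 200 probe sets of values drawn from the arrays' own spread. Of the 67, 67 and 66 changed by log2 values of 0.5, 1 and 2, 65, 60 and 54 passed the filter, and the test over 31526 probe sets recovered 12.3%, 53.3% and 81.5% of these, with 3 false calls, and camera called the 1 list that was shifted and 0 others. The simulated probe sets varied independently of each other, so camera was not tried on correlated genes. Only 200 were changed, against 9577 called in the data, so these recoveries need not hold there. The alternatives tried were offsets of 1 and 100, the values as deposited and median centring in place of quantile normalization, no filter and a filter at the 50th percentile, eBayes without the trend, array weights, the replicate letter as a block, leaving out each array, thresholds of 0.01 and 0.1, a fold minimum of 2, 1 probe set per gene, an estimated correlation, fry in place of camera, and the mean of all probe sets of a gene.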

Results

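Gene expression was measured in mouse megakaryocytes, the cells that shed platelets into the blood, from a Gata-1 knock down and from wild type. GATA1 is a zinc finger transcription factor needed for the maturation of megakaryocytes and red cells. Per the labels, progenitors from fetal livers of embryonic day 13.5 were grown into megakaryocytes, which were then collected on a bovine serum albumin gradient. There were 6 arrays, 3 of knockdown and 3 of wild-type cells, named by the letters A, B and C in each group. The deposited signal of the middle probe set of an array was 111.3, 137.8 and 118.4 for knockdown A, B and C, and 101.6, 104.4 and 101.8 for wild type A, B and C. Correlations of log2 values across probe sets, which are not independent replicates, were 0.980 to 0.981 within wild type, 0.963 to 0.974 within knockdown and 0.942 to 0.957 between the groups. Knockdown B stood apart from the others with the highest median and, at 132, the highest bacterial control signal, against 60.7 to 82.2 on the other 5 arrays. The number of arrays limits the precision. The labels do not say whether the samples came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

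The first question was whether Gata1 itself was lower in the samples labelled knockdown. The 1 probe set of Gata1 read 153.5, 143.3 and 194.7 in the knockdown samples and 8723.7, 8246.5 and 8495.6 in wild type. Its mean signal was 164 ± 27.2 in knockdown and 8489 ± 239 in wild type (SD, n = 3 each). On the scale tested the log2 fold change was -5.52 ± 0.12 (SE), or 45.9-fold lower, with a limma adjusted p of 2.89e-09. The knockdown signal was above that of the bacterial controls on each knockdown array.

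The second question, posed by the series title, was how expression differed between the groups. Of 14230 genes tested, 2606 were higher and 2439 were lower in knockdown, and large changes were mostly falls: 731 genes were lower by at least 2-fold and 295 were higher, 139 were lower by at least 4-fold and 27 higher, and 35 were lower by at least 8-fold and 4 higher. These are fitted changes, and with signals floored at the bacterial controls, a step added after these counts were seen, 643 and 267, 114 and 25, and 34 and 4 genes remained past these limits. Over probe sets, 9577 of 31526 passed an adjusted p of 0.05 with limma and Benjamini-Hochberg adjustment, 30.4% of those tested, with 5062 higher and 4515 lower. The split between rises and falls depended on the scaling of the arrays, since 52.9% of calls were rises here, 32.9% with arrays centred on their medians and 60.0% with the values as deposited.

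The largest rise was that of the stress-inducible heat shock gene Hspa1b, from 140 ± 20.2 in wild type to 4396 ± 38.4 in knockdown (SD, n = 3), a log2 fold change of 4.65 ± 0.09 (SE). Its neighbour and near-identical copy Hspa1a rose by 3.28 ± 0.13, and probes for these genes may read either transcript. Gbp6, an interferon-inducible GTPase, rose by 3.39 ± 0.11, the organic anion transporter Slco2b1 by 3.26 ± 0.08 and the ciliary gene Ahi1 by 2.95 ± 0.08. The crosslinking enzyme transglutaminase Tgm2 rose by 2.63 ± 0.09, the metal-binding protein Mt2 by 2.57 ± 0.07, the inhibitory Fc receptor Fcgr2b by 2.55 ± 0.12 and the Cdc42 effector Cdc42ep1 by 2.52 ± 0.15. Ift74, of intraflagellar transport, rose by 2.50 ± 0.12 and the desmosome protein Dsp by 2.50 ± 0.10. The calcium channel subunit Cacna2d1 lay within background in wild type and was at least 6.92-fold higher in knockdown (adjusted p 2.56e-06, limma). All 12 of these genes were higher on each knockdown array than on any wild-type array, and the highest limma adjusted p among them was that of Cacna2d1.

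Among the genes with the largest falls besides Gata1 were 4 that lay within background in knockdown, so that their falls are bounds and have no rank. The glutathione transferase Gsta2 read 1986 ± 95.7 in wild type and was at least 22.3-fold lower in knockdown. Sardh, the mitochondrial sarcosine dehydrogenase, was at least 14.4-fold lower, the myosin regulatory light chain Myl9 at least 18.6-fold lower and the potassium channel subunit Kcnf1 at least 9.89-fold lower. The log2 fold changes were -4.30 ± 0.14 (SE) for Prrt4, -4.30 ± 0.25 for the imprinted gene Mest, -4.20 ± 0.14 for Gramd1c and -4.20 ± 0.09 for the extracellular glycoprotein Reln. The inflammatory caspase Casp4 changed by -4.05 ± 0.12, from 4558 ± 769 to 249 ± 17.3 (SD, n = 3), and Ifit1, induced by interferon, by -4.0 ± 0.10. Hjv, which encodes hemojuvelin, a coreceptor in iron sensing, changed by -3.99 ± 0.11. The highest limma adjusted p among these 12 genes, Gata1 included, was 9.73e-07, for Mest, and all 12 were lower on each knockdown array than on any wild-type array.

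**Figure D1:**
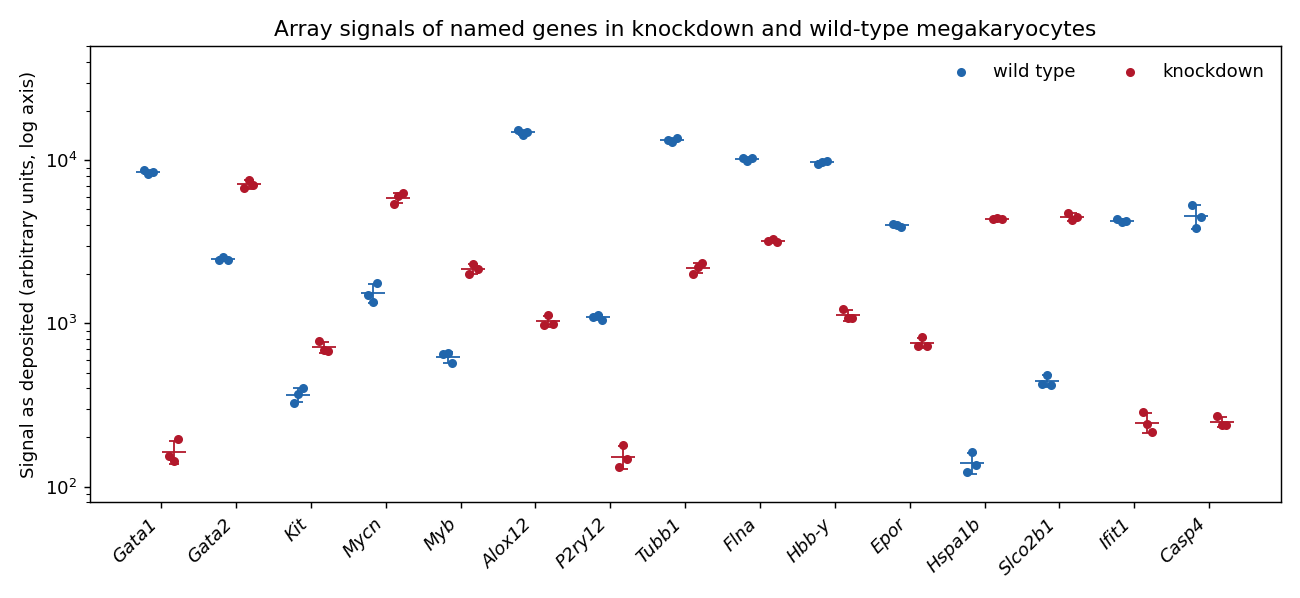
Signal as deposited on each array, in arbitrary units on a log axis, for 15 genes in wild type (blue) and knockdown (red), with points for the 3 arrays of a group and a bar and whiskers for their mean ± SD. Gata1 lay between 143.3 and 194.7 in the 3 knockdown samples and between 8246.5 and 8723.7 in wild type.

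Genes of the megakaryocyte's own products were mostly lower in knockdown. Among 30 tested genes for platelet receptors and granule proteins, 24 fell, 2 rose and 4 did not pass the test (25 fell and 2 rose when adjusted over the list alone), with a median log2 fold change of -0.53 and a camera adjusted p of 3.70e-10. The 12-lipoxygenase gene Alox12 went from 14821 ± 555 to 1032 ± 85.5 (SD, n = 3; log2 fold change -3.92 ± 0.07 SE), the ADP receptors P2ry12 and P2ry1 changed by -2.71 ± 0.11 and -2.67 ± 0.09, and coagulation factor gene F5 by -1.82 ± 0.08. The 2 that rose, named after their values were seen, were the thromboxane receptor Tbxa2r, by 0.82 ± 0.10, and the signalling regulator Rgs18, by 0.21 ± 0.04, a call lost with arrays centred on their medians. Clec1b, Plek and Cd9, counted among the falls, had higher mean signals in knockdown as deposited, and their log2 fold changes of -0.21, -0.17 and -0.17 arose on quantile normalization. Pf4 and Itga2b, named after their values were seen, did not pass, at -0.06 ± 0.04 and -0.03 ± 0.06 (limma adjusted p 0.304 and 0.812). Their wild-type means, 17120 ± 811 and 18477 ± 662, lay near the highest signals of those arrays, 21182 to 23171. A ceiling on their signals was not excluded. Of 28 genes of the cytoskeleton and of proplatelet formation, 18 fell, 0 rose and 10 did not pass (19 and 0 when adjusted over the list alone; median -0.37, camera adjusted p 8.39e-07). Besides Myl9, these included the platelet beta-tubulin Tubb1, at -2.61 ± 0.06, the actin crosslinker Actn1 at -1.99 ± 0.07 and filamin A, Flna, at -1.62 ± 0.05, while the fall of the actin-binding Pfn1, -0.15, also arose on normalization. Without knockdown C, 1 gene of this list rose. With the values as deposited, 14 genes of this list fell and 1 rose, and 19 genes for platelet receptors and granule proteins fell and 2 rose.

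Red cell genes changed in both directions. Among 26 tested genes for hemoglobins and red cell proteins, 5 rose, 5 fell and 16 did not pass, with the same counts when adjusted over the list alone, a median log2 fold change of -0.09 and a camera adjusted p of 0.278. Only 13 of the 26 exceeded 3 times background in wild type, so a gene that did not pass may be too dim to show a change. The embryonic globin gene Hbb-y changed by -3.07 ± 0.06, from 9748 ± 197 to 1126 ± 87.0 (SD, n = 3), and the erythropoietin receptor Epor by -2.34 ± 0.08. The sialoglycoprotein gene Gypc changed by -1.23 ± 0.06, the water channel Aqp1, within background in knockdown, was at least 2.0-fold lower, and the spectrin gene Sptb changed by -0.65 ± 0.15. Those that rose were the blood group genes Xk, by 0.89 ± 0.15, and Kel, by 0.61 ± 0.17, with Car2, Mgst3 and Slc4a1, by 0.45 ± 0.06, 0.43 ± 0.07 and 0.35 ± 0.09. Sptb and the 5 that rose were named after their values were seen, and 2 genes of this list rose with arrays centred on their medians and 3 without wild type C. The call of Kel was lost without knockdown B or wild type C, and that of Slc4a1 without knockdown C or any 1 of the wild-type arrays. Of 19 genes for heme synthesis and iron uptake, 3 rose, 8 fell and 8 did not pass, also when adjusted over the list alone (median -0.14, camera adjusted p 0.167). With the mean of all probe sets of a gene, camera called this list lower (median -0.24, adjusted p 0.0277). Alad, of heme synthesis, rose by 0.96 ± 0.09 and the mitochondrial iron carrier Slc25a37 by 0.73 ± 0.09, with Uros, named after its value was seen, at 0.36 ± 0.12, a call lost when any 1 array but knockdown A was left out. Aco1, whose protein binds iron-responsive elements, changed by -0.93 ± 0.16, and the biliverdin reductase Blvrb by -0.92 ± 0.06.

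Stem and progenitor genes were more often higher. Of 25 tested, 13 rose, 4 fell and 8 did not pass (14 and 4 when adjusted over the list alone), with a median log2 fold change of 0.41 and a camera adjusted p of 0.00198. The median was 0.183 with no filter, 0.252 with arrays centred on their medians and 0.778 with the filter at the 50th percentile. The adjusted p was 0.0883 with an estimated correlation, so this list's call was lost there. Mycn rose by 1.98 ± 0.09, Myb by 1.73 ± 0.09 and Gata2, the related GATA factor of early progenitors, by 1.57 ± 0.06, from 2480 ± 75.8 to 7143 ± 457 (SD, n = 3). The stem cell factor receptor Kit rose by 0.84 ± 0.11. Ikzf2 changed by -1.61 ± 0.09, and Hhex, Sox4 and Mllt3, named after their values were seen, by -0.74 ± 0.07, -0.64 ± 0.14 and -0.63 ± 0.12.

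Megakaryocyte and erythroid transcription factors had no common direction. Of 31 tested, 10 rose, 6 fell and 15 did not pass (11 and 7 when adjusted over the list alone), and the median of 0.05 and the mean of -0.04 differed in sign (camera adjusted p 0.473). Gata1 itself, at -5.52, is in this list, counts among the 6 falls and enters the mean. The counts turned over to 6 that rose and 10 that fell with arrays centred on their medians, and 3 fell without wild type B or wild type C. Mrtfa, a cofactor of serum response factor, changed by -2.83 ± 0.07, while the ETS factor Ets1 rose by 2.47 ± 0.16, from 105 ± 12.6 to 800 ± 175 (SD, n = 3). Nfe2, a factor of late megakaryocytes, changed by -0.32 ± 0.05. The GATA1 partner Zfpm1 rose by 0.29 ± 0.04, a call that was lost with arrays centred on their medians, where the value was 0.08 and the limma adjusted p 0.530. The ETS factor Fli1 had a log2 fold change of -0.16 ± 0.14 (limma adjusted p 0.464), and without knockdown A, which read 4778.0 against 2986.5 and 3248.0 in the other knockdown samples, it was -0.37 with an adjusted p of 0.000396. Spi1 had -0.23 ± 0.13 (limma adjusted p 0.209), and was called at -0.36 without knockdown B and at -0.37 with arrays centred on their medians (adjusted p 0.0253 and 0.0315).

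Genes of DNA replication and mitosis were more often higher than lower, mostly by small amounts. Of 37 DNA replication genes, 22 rose, 0 fell and 15 did not pass (24 and 0 when adjusted over the list alone; median 0.30, camera adjusted p 3.17e-06), and 1 fell without knockdown A. Examples were the licensing factor Cdt1, at 0.84 ± 0.07, the clamp loader subunit Rfc3 at 0.76 ± 0.11, Orc6 at 0.64 ± 0.07 and Rpa2 at 0.63 ± 0.09. Of 34 mitosis genes, 21 rose, 1 fell and 12 did not pass (23 and 1 when adjusted over the list alone; median 0.40, camera adjusted p 1.82e-05). The spindle protein Prc1 rose by 1.04 ± 0.14, Bub1b by 0.62 ± 0.09 and Kif11 by 0.58 ± 0.10, and the kinase Nek2, named after its value was seen, changed by -0.41 ± 0.09. Top2a rose by 0.56 ± 0.08, and its limma adjusted p was 0.134 with arrays centred on their medians. Under that centring 8 DNA replication genes rose and 1 fell, and 5 mitosis genes rose and 2 fell, while the camera calls held with adjusted p of 0.00151 and 0.00174. Among 27 cyclins, CDKs and CDK inhibitors, 9 rose, 4 fell and 14 did not pass, also when adjusted over the list alone (median 0.06, camera adjusted p 0.223). Cdk4 rose by 1.05 ± 0.08, while cyclin D1, Ccnd1, changed by -1.47 ± 0.16 and the inhibitors Cdkn1b and Cdkn1c by -1.08 ± 0.18 and -0.94 ± 0.14. The last of the 4 falls was Cdkn2d, at -0.23 ± 0.04, while the inhibitor Cdkn1a rose by 0.88 ± 0.05, both named after their values were seen. Cdkn2a had a log2 fold change of 0.01 ± 0.23 (limma adjusted p 0.978).

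Markers of myeloid cells were lower in knockdown. Of 27 neutrophil and monocyte markers, 20 fell, 2 rose and 5 did not pass (22 and 2 when adjusted over the list alone; median -1.29, camera adjusted p 9.95e-10). The antimicrobial protein genes S100a9, Ngp, Lcn2 and S100a8 changed by -2.23 ± 0.12, -2.17 ± 0.10, -2.02 ± 0.15 and -1.96 ± 0.08. The brightest markers of this list in wild type, Lyz1 and Lyz2, named after their values were seen, changed by only -0.30 ± 0.04 and -0.32 ± 0.04. The 2 that rose, named after their values were seen, were the oxidase subunits Ncf4, by 0.74 ± 0.07, and Ncf1, by 0.69 ± 0.05. Of 25 macrophage markers, 22 fell, 1 rose and 2 did not pass (22 and 2 when adjusted over the list alone; median -1.21, camera adjusted p 4.26e-11). The lipid receptor Cd36 changed by -1.83 ± 0.08 and the Fc receptor Fcgr1 by -1.78 ± 0.10. The brightest macrophage markers in wild type, Gpnmb and Lgals3, named after their values were seen, changed by -1.09 ± 0.06 and -0.73 ± 0.06. Cd5l, at or below the bacterial controls on 2 of the 3 knockdown arrays, was at least 5.29-fold lower, and Aif1, within background in knockdown, at least 3.43-fold lower. Apoe, named after its value was seen, rose by 1.33 ± 0.07. Of 25 markers of mast cells, basophils and eosinophils, 14 fell, 4 rose and 7 did not pass (16 and 4 when adjusted over the list alone; median -0.78, camera adjusted p 0.000377). The mast cell protease gene Mcpt2, at or below the bacterial controls on 2 of the 3 knockdown arrays, was at least 9.60-fold lower, and Mcpt1, Mcpt4 and the histidine decarboxylase gene Hdc, within background in knockdown, were at least 5.26-fold, 2.42-fold and 2.44-fold lower. The brightest of this list in wild type, also named after their values were seen, were Slc6a4, at -1.24 ± 0.04, and Fcer1g, at -0.00058 ± 0.04 and not called. Besides Kit, the vesicular amine transporter Slc18a2 rose by 1.95 ± 0.07, Hpgds by 0.72 ± 0.13 and Alox5 by 0.45 ± 0.06, all named after their values were seen.

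Markers of other cells that a fetal liver holds were not shifted as lists. Most hepatocyte and lymphoid markers were dim, so their lists say little about these cells. Only 1 hepatocyte and 4 lymphoid markers exceeded 3 times background in wild type, with median log2 fold changes of -1.35 and -0.48. Of 17 hepatocyte markers, 2 fell, 0 rose and 15 did not pass, also when adjusted over the list alone, with a median of 0.03 although camera put the list's direction downward (adjusted p 0.431). Afp changed by -1.35 ± 0.18 and Rbp4 by -0.77 ± 0.19, and without wild type B the limma adjusted p of Rbp4 was 0.0611. Without knockdown A, 2 markers of this list rose. Of 21 endothelial and stromal markers, 3 rose, 4 fell and 14 did not pass (4 and 4 when adjusted over the list alone; median -0.07 and mean 0.01, camera adjusted p 0.694). The endothelial receptors Kdr and Tie1 rose by 1.54 ± 0.14 and 1.38 ± 0.11 and the collagen gene Col4a1 by 1.03 ± 0.19, while Timp3 changed by -1.03 ± 0.08. Vim, Lyve1 and Flt1, named after their values were seen, changed by -1.01 ± 0.07, -0.92 ± 0.14 and -0.57 ± 0.19, and the call of Flt1 was lost when any 1 array but knockdown A was left out. Of 18 lymphoid markers, 0 rose, 3 fell and 15 did not pass (0 and 2 when adjusted over the list alone; median -0.09, camera adjusted p 0.431). Blnk changed by -1.09 ± 0.17 and Il7r by -0.89 ± 0.11. Klrd1 was within background in knockdown and at least 1.10-fold lower (limma adjusted p 0.0377), a call that was lost without knockdown A, knockdown B or any 1 of the wild-type arrays and under 4 other settings (adjusted p 0.0538 to 0.120).

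The interferon response list had the lowest camera adjusted p of the 20 lists tested. Of 29 genes, 26 fell, 1 rose and 2 did not pass, also when adjusted over the list alone, with a median log2 fold change of -0.92 and an adjusted p of 1.00e-12. Next to Ifit1, the guanylate-binding protein gene Gbp2 changed by -3.40 ± 0.14 and Ifit3 by -3.31 ± 0.31, and the antiviral GTPase gene Mx2, within background in knockdown, was at least 2.87-fold lower. The gene counted as a rise was Xaf1, named after its values were seen. Its brighter probe set rose by 1.87 ± 0.11 and its other probe set changed by -2.99 ± 0.16. When knockdown A, knockdown B or knockdown C was left out, 0 genes of the list rose. Each of those fits chose the brightest probe set of a gene anew, so the probe set counted for Xaf1 can differ there.

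Of 20 cholesterol synthesis genes, 16 fell, 1 rose and 3 did not pass, also when adjusted over the list alone (median -0.44, camera adjusted p 2.50e-06, and adjusted p 0.0610 with an estimated correlation, so that the call was lost there). Tm7sf2, Insig1, Lss and Ebp changed by -1.68 ± 0.11, -1.15 ± 0.11, -1.03 ± 0.07 and -0.96 ± 0.08, though only 1 of the 3 tested probe sets of Lss was called. The transport protein gene Stard4, named after its value was seen, rose by 0.27 ± 0.05 but was at -0.02 and not called with arrays centred on their medians. Of 24 glycolysis and hypoxia genes, 11 rose, 5 fell and 8 did not pass (14 and 5 when adjusted over the list alone; median 0.30, camera adjusted p 0.0185). The adjusted p was 0.118 with an estimated correlation. Bnip3, Aldoc and Ankrd37 rose by 1.41 ± 0.07, 1.32 ± 0.08 and 1.14 ± 0.19, and Ndrg1 changed by -1.76 ± 0.05. The other falls, named after their values were seen, were Slc2a1, Pfkm and Hk1, at -0.53 ± 0.06, -0.31 ± 0.08 and -0.25 ± 0.05, and Ldha at -0.21 ± 0.04, whose mean signal as deposited was higher in knockdown. The call of Pfkm was lost without wild type A or wild type C. With arrays centred on their medians 7 genes of this list rose.

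Among 20 genes of endoplasmic reticulum stress and the unfolded protein response, 12 fell, 4 rose and 4 did not pass (13 and 4 when adjusted over the list alone; median -0.36, camera adjusted p 0.0109). The adjusted p was 0.136 with an estimated correlation and 0.0558 with the mean of all probe sets of a gene, so the call was lost under each. Ddit3 changed by -1.14 ± 0.07 and the chaperone partner Sdf2l1 by -1.12 ± 0.06, while Trib3 rose by 1.93 ± 0.09 and the asparagine synthetase gene Asns by 1.18 ± 0.06. Chac1 and Atf4, named after their values were seen, rose by 1.12 ± 0.11 and 0.37 ± 0.05. Atf4 lost its call with arrays centred on their medians. Of 25 immediate early and AP-1 genes, 9 rose, 10 fell and 6 did not pass (9 and 11 when adjusted over the list alone; median -0.11, camera adjusted p 0.167). Fosb, Dusp1, Fos and Fosl2 changed by -1.98 ± 0.14, -1.89 ± 0.06, -1.75 ± 0.08 and -1.52 ± 0.20, while Nr4a1, Klf2 and Myc, named after their values were seen, rose by 0.99 ± 0.13, 0.78 ± 0.09 and 0.78 ± 0.08.

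Of the sex-linked genes, Xist rose by 0.66 ± 0.05, from 4861 ± 54.4 to 7279 ± 358 (SD, n = 3). The Y-linked Eif2s3y, Kdm5d and Uty were measured in both groups, with log2 fold changes of 0.33 ± 0.15, 0.38 ± 0.15 and -0.03 ± 0.11 (limma adjusted p 0.127, 0.0923 and 0.863). Without knockdown B, Eif2s3y and Kdm5d were called at 0.48 and 0.51 (adjusted p 0.0193 and 0.0210). With array weights their adjusted p was 0.0446 and 0.0384, and Kdm5d was also called with the values as deposited, at 0.51 (adjusted p 0.0233).

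**Figure D2:**
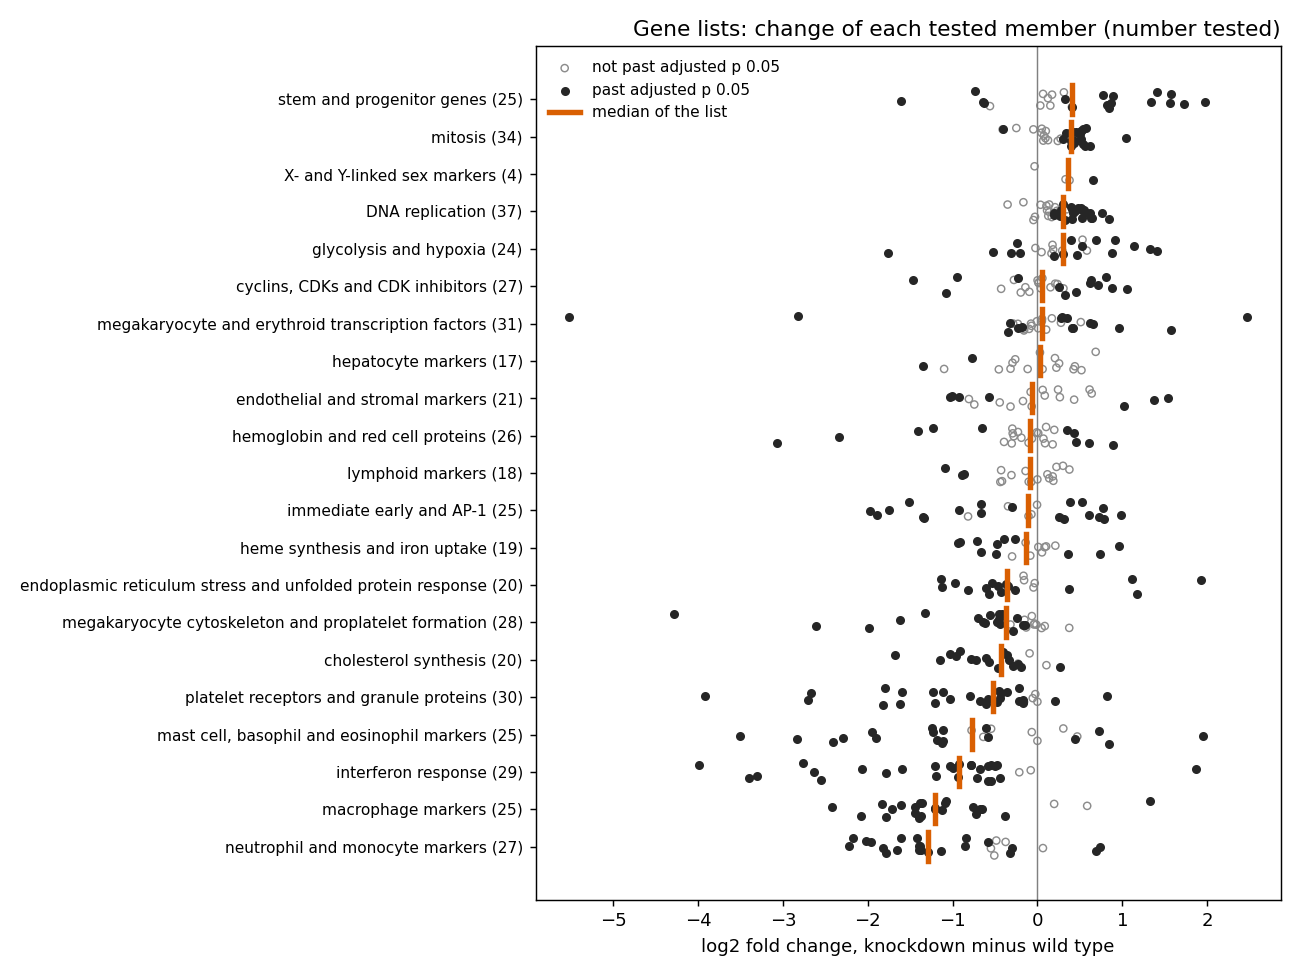
Log2 fold change, knockdown minus wild type, of each tested member of the 21 lists on the horizontal axis, with filled points past a limma adjusted p of 0.05, open points not past it and a bar at each list's median. Medians ran from -1.29 for neutrophil and monocyte markers to 0.41 for stem and progenitor genes.

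Over the 20 lists tested with camera, 12 passed an adjusted p of 0.05 with the preset correlation. With a correlation estimated for each list 8 did: platelet receptors, cytoskeleton, DNA replication, mitosis, the 3 lists of myeloid markers and interferon response. The lists were fixed from general knowledge before the data were examined.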

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

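The alternatives were fixed before the data were examined. Gata1 stayed called and lower under all of them, with log2 fold changes of -5.79 to -5.07. Of the 100 called genes besides Gata1 that the rule fixed in advance names, 96 stayed called in the same direction under every alternative that tested them, and the others were Klrd1, Rbp4, Zfpm1 and Top2a. Of 60 called genes named after their values were seen, Lyz1, Lyz2, Gpnmb, Lgals3 and Slc6a4 aside, 40 did so under every alternative. Clec1b, Plek, Cd9, Pfn1 and Ldha changed sign with the values as deposited and Stard4 with median centring, Sphk1 was left out by the filter at the 50th percentile, and Rgs18, Car2, Mgst3, Slc4a1, Kel, Uros, Cdkn2d, Alox5, Flt1, Pfkm, Hk1, Atf4 and Ccl25 lost their call under at least 1. Calls of probe sets numbered 7383 to 10709 when 1 array was left out, against 9577.

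With arrays centred on their medians 2609 probe sets were higher and 5333 lower, so that 32.9% of calls were rises, against 52.9% in the fit reported and 60.0% (6259 higher, 4167 lower) as deposited. The median log2 fold change of all probe sets tested was 0.109 further up as deposited and shifted by -0.0867 with median centring, relative to the fit reported. With a change of at least 2-fold required, 2122 probe sets were called, 694 higher and 1428 lower. With 1 probe set per gene there were 5045 calls, 2606 higher and 2439 lower, which follows from the smaller number tested.

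Some small values that were not called changed sign. Uty was at 0.0752 as deposited and at -0.0668 to 0.00825 when 1 array was left out, and Cdkn2a at -0.0951 to 0.130 when 1 array was left out (-0.0554 without knockdown A). Camera's direction turned with median centring for the transcription factor list (median -0.137), hepatocyte markers (median 0.0266) and endothelial and stromal markers (median -0.141), and for the last also with no filter (median 0.0738). The cause was not tested. Medians of lists that camera called moved over 1.5-fold for stem and progenitor genes, as given in the report, for the cytoskeleton as deposited (-0.222), and with median centring for DNA replication (0.177), mitosis (0.163), glycolysis (0.140), cholesterol synthesis (-0.673) and endoplasmic reticulum stress (-0.547). Those of the 8 lists that camera did not call moved over 1.5-fold as well. Camera called 8 lists with an estimated correlation and 12 under its other alternatives, though not always the same ones: with the mean of all probe sets of a gene, heme synthesis was gained (adjusted p 0.0277) and endoplasmic reticulum stress lost (0.0558). Fry, which asks whether a list's own genes move without comparing them with other genes, called 19 lists. It gave the transcription factors (median 0.0517), a list that holds Gata1 itself, the opposite direction to camera.

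The letters A, B and C did not pair the samples. Deviations of samples with the same letter correlated at -0.0423, -0.0174 and -0.00958, and 0 of 6 samples correlated best with their own letter. With the letter as a replicate block 8757 probe sets were called, 4591 higher and 4166 lower, and Gata1 was at -5.52. Signal over background limits the dim genes, for which folds are bounds.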

Other observations

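Several gene families, some of whose members are also in the lists, were looked at after the results were seen, with limma's adjusted p. Glutathione transferases did not move together: of 18 tested, 3 rose and 4 fell. Besides Gsta2, Gstt1 went from 12931 ± 319 to 864 ± 49.9 (SD, n = 3), a log2 fold change of -3.91 ± 0.06 (SE), while Gstm5 rose by 0.78 ± 0.15. Of 8 caspases, 4 fell and 2 rose: besides Casp4, Casp12 and Casp1, each at or below the bacterial controls on 2 of the 3 knockdown arrays, were at least 4.30-fold and 3.69-fold lower, while Casp2 rose by 1.13 ± 0.09. The guanylate-binding proteins split, with Gbp6 and Gbp8 rising by 3.39 ± 0.11 and 1.24 ± 0.19 and Gbp2 and Gbp7 changing by -3.40 ± 0.14 and -1.46 ± 0.06, while Gbp3, as dim in knockdown, was at least 6.18-fold lower. Of 9 SLAM family receptors 5 fell and 0 rose, led by Slamf1, which went from 6947 ± 55.5 to 651 ± 20.9. Of 13 CC chemokines 7 fell and 1 rose, with Ccl6 and Ccl9 at -2.71 ± 0.07 and -2.68 ± 0.07 and Ccl25 at 0.73 ± 0.21, a call lost without knockdown C, wild type B or wild type C. The metallothioneins Mt1 and Mt2 rose by 1.57 ± 0.06 and 2.57 ± 0.07. Of the 40 called members of these families and the 70 kDa heat shock proteins, 37 stayed called in the same direction with the values as deposited and 35 with median centring, and 0 changed sign.

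The tests reported from here on were chosen after the results they bear on had been seen, though the scalings they use were among the alternatives fixed in advance. The difference between the groups was set against the other ways of splitting the 6 samples into 3 and 3. The real split called 9577 probe sets and the highest of the other 9 called 0 with limma, and at an unadjusted p under 0.05 the real split gave 12341 and the others 410 to 1050. Of the 10 splits 1 gave a count as large, and 10 are too few for a share under 0.05. Each of the other 9 also mixes knockdown and wild-type arrays, so the difference between the groups widens their spread and makes calls unlikely.

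Interferon response genes were lower in knockdown. The scaling of the arrays is argued against as the cause, since the list's median was -0.855 or lower under each of the 3 scalings. A lower share of macrophages and neutrophils, which express many of these genes, may account for the fall. The interferon median lay 0.291 above the macrophage marker median, with a bootstrap standard error of 0.235, so the list's median was no lower than that of the markers. Of its members 6 had fitted falls beyond that of Cd5l, the steepest among the macrophage and neutrophil markers, and for Ifit1 and Gbp2 the gap exceeded 2 standard errors of each. The fall of Cd5l is only a bound, so this cannot be read as a deeper fall. The tests leave this open, as they leave open an effect of lower Gata1 within the megakaryocytes, which was not tested.

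Markers of macrophages, neutrophils and mast cells were lower in knockdown, and 1, 1 and 2 of the tested markers are also in another list. The scaling of the arrays is argued against, since the least negative of the 3 medians over the scalings was -0.696. A loss of every kind of other cell would lower other markers as far. Erythroid, lymphoid and hepatocyte markers above 3 times background had a pooled median 1.32 above that of macrophage markers (bootstrap standard error 0.311). That result rests on the 13 erythroid genes among 18, since the 4 lymphoid genes had a median of -0.48 and the 1 hepatocyte gene -1.35. The bright erythroid genes Hbb-y and Epor changed by -3.07 and -2.34, against a macrophage marker median of -1.36. Of all 26 tested red cell genes, 5 fell and 5 rose. The pooled median therefore cannot decide against a loss of every kind of other cell. A lower share of these myeloid cells alone also cannot be told apart from lower expression. Of the 62 called markers 88.7% fell, but the called macrophage markers differed among themselves with an SD of 0.731 against a median standard error of 0.0962. These comparisons replaced an earlier one, of the spread of the macrophage markers alone, which could not decide, and how many of the markers megakaryocytes express after the gradient step is not known from these data.

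Genes next to each other on a chromosome changed together more often than in shuffled orders. With the gene order of the GRCm38.p6 assembly, 10 pairs of adjacent tested genes both had fitted changes over 4-fold, against a mean of 1.93 in 2000 shuffled orders, a permutation p of 5e-04, the smallest these can give. Of these, 7 joined related genes (Ccl9 with Ccl6, Mcpt1 with Mcpt2 and Mcpt2 with Mcpt4, Hspa1b with Hspa1a, Ifit2 with Ifit3, Casp1 with Casp4 and Casp4 with Casp12). Probe sets with a suffix such as _a_at, _s_at or _x_at, which can mark shared probes, were then left out. There were again 7 related pairs, with S100a4 and S100a9 in place of Mcpt2 and Mcpt4. S100a4 and S100a9 were not a pair with all probe sets, so theirs is a new pair, while the others were retained. This argues against the suffixed probe sets as the whole cause. The other probe sets may still read a related gene, as said of Hspa1b and Hspa1a, so shared probes are not excluded. Some of these genes were near background in knockdown, where 4-fold is not shown. With signals floored at the bacterial controls 6 pairs remained, 5 of them related, against a shuffled mean of 1.35 (permutation p 0.003). With floored signals and without the suffixed probe sets there were 6 related pairs, the new pair of S100a4 and S100a9 among them. The pairs of unrelated genes, Lypd1 with Nckap5, Slc30a1 with Traf5 and Sphk1 with Ube2o, numbered 3 against a shuffled mean of 1.84 (permutation p 0.279). With floored signals only Slc30a1 with Traf5 remained, 1 against 1.28 (permutation p 0.732). With the suffixed probe sets left out as well there were 2 unrelated pairs against 1.08 (permutation p 0.29). Chromosome segments of another strain could thus not be told apart from chance. Of the 60 genes nearest to Gata1, 31.7% were called against 35.5% of all (Fisher's exact p 0.591), and 0 changed over 4-fold.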
